A study of Rattus norvegicus with 6 samples.

How the data were processed

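Total RNA of 6 implants was analysed on Illumina bead arrays, with 3 rats at day 1 and 3 at day 3. Per the labels' protocols, RNA was isolated from the implants, treated with DNase, amplified from 100 ng and labelled with biotin. The deposited values are intensity values on a linear scale, 1 per probe and array, for 22517 probes. The submitters' processing notes name limma, with no version. The deposited intensity values had already been quantile normalized: the sorted columns of the 6 arrays differ by at most 0.535 units, or 0.0399%. Their median is 104.045 on every array, so neither scale nor centring differs between arrays, and whether the authors corrected the background is not given in the sources used here. No 2 arrays held the same values; at most 0.107% of probes were equal between any pair.

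A second deposited table holds values before normalization, with detection p-values. Its 12 columns of per-sample values (6 of signal and 6 of detection p-values) have headers that match no label, so they were not used here. The design fixed before the data were examined provided for this case: the normalized table took its place, and no detection p-value entered the filter. The planned detection filter and the background step based on detection p-values were therefore not run.

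Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log2 was taken. No further normalization between arrays was applied. Probes above their array's median on at least 3 of 6 arrays were kept, which left 11591. Groups came from the labels, and the rats of the 2 groups carry different numbers, so no pairing entered. Each probe was tested with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The fold changes are on the scale of the offset signal and understate the change of dim probes. For a probe at or below the array median on every array of 1 day, the fold is given as a lower bound, the bright day's mean against the higher of each dim array's median and the probe's own signal.

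Probe names came from the platform annotation. Of the probes, 13787 have 1 gene symbol, 0 have several and 8730 are unnamed here. Symbols were checked through Entrez identifiers against the rat assembly GRCr8, which was used for names only. Of the named probes, 13747 matched and 40 did not, and 0 symbols changed. The kept probes include 3085 unnamed ones and stand for 8352 named genes. For 148 genes with several kept probes, the probe with the highest mean signal stands for the gene in lists. None of the 148 was called in both directions, and 42 were called by some probes only.

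The 30 gene lists and the rule for named genes were fixed before the data were examined. The rule takes genes with adjusted p under 0.05 whose days do not overlap and whose symbol is not provisional, the 8 with the largest rise and the 8 with the largest fall. From each list it takes the 2 called members with the largest absolute change, or the member with the smallest p where none was called. It gave 73 entries and 66 distinct genes, and other list members are named as examples chosen after their values were seen. List members were matched by symbol, then by older symbol, then by a synonym that no other gene holds. The last condition was added after values of the lists had been seen, because 2 members had been matched to wrong genes; the lists themselves were not changed. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 30 lists.

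The fits were tested on simulated data for this comparison, with 100 probes changed 2-fold and 100 changed 4-fold on the rats' own spread, over 11481 tested probes. The test recovered 24% of the 2-fold and 68% of the 4-fold changes, and 7 of 99 calls were false (7.07%). No recovered change had the wrong direction. An 80% bar on the 4-fold changes, set in advance, was not met and was dropped. A second simulation with larger changes added was then tried and set aside, and the results of the first are the ones given. Among the 4-fold changes, the fitted log2 change was 0.505 of the true one in the dimmest of 3 classes of brightness, 0.819 in the middle class and 0.961 in the brightest. With 100 random lists, camera gave 3 with a p under 0.05. The simulated probes varied independently, so this does not test camera on lists of correlated genes. The cell cycle list, for example, had an estimated correlation of 0.472. Far fewer probes were changed in the simulation than the 3694 called in the data, so the recovered percentages may not carry over.

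The alternatives planned were no background correction, no filter, a filter on all 6 arrays, array weights, an intensity trend with robust fitting, stricter thresholds, each rat left out in turn, and for lists the other tests and the mean of a gene's probes. Added after seeing the data were cyclic loess on top of the deposited values, offset 16, and the 2 arrays with high muscle signal left out together. Lists written after the main results, for the closing part, hold pan-leukocyte genes, cholesterol and fatty acid synthesis genes, protein folding and secretory pathway genes, a second set of skeletal muscle genes and resident subcutaneous tissue genes. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.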

Results

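Gene expression was measured in granulation tissue, the new tissue of a healing wound, that had formed in cellulose implants coated with hydroxyapatite, a calcium phosphate mineral. The implants lay under the skin of Sprague-Dawley rats aged 10 weeks. Total RNA from 6 implants of 6 different rats was hybridised to Illumina bead arrays with 1 colour. Implants were taken at 24 hours (day 1, rats 1, 2 and 3) or at 72 hours (day 3, rats 6, 4 and 7), so each group had n = 3. The limma p-values of single probes measure the spread between these rats, and the number of arrays limits the precision. Camera p-values at the preset correlation compare a list's genes with other genes and treat genes as nearly independent. Their size therefore also follows the number of genes and does not measure the spread between rats alone. Signals are normalized log2 values, given as mean ± SD, and a change is day 3 minus day 1.

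The comparison of day 3 with day 1 asks which genes differ between these early times of granulation tissue formation. At day 3, 24 of 27 collagen and matrix genes and 31 of 37 cell cycle genes were higher, and 13 of 17 neutrophil markers, 15 of 22 inflammatory mediators and 15 of 25 hypoxia response and glycolysis genes were lower. Camera called each of these lists at the preset correlation only (adjusted p = 0.413 for the hypoxia list and 0.377 for the others with an estimated correlation). Cthrc1, a secreted protein of matrix-forming cells, rose 61.4-fold, from 7.12 ± 0.77 to 13.06 ± 0.15 (SD, n = 3). Col1a1, which encodes a chain of type I collagen, rose 35.5-fold, from 9.31 ± 0.74 to 14.46 ± 0.12. Retnlg, a secreted protein of rodent neutrophils, fell 8.94-fold, from 13.33 ± 0.44 to 10.17 ± 0.37 (SD, n = 3).

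Of 11591 probes tested, 3694 changed (31.9%; limma with Benjamini-Hochberg adjustment), with 1937 higher and 1757 lower at day 3. These probes stand for 2908 named genes. A change of at least 2-fold was seen for 832 higher and 731 lower probes, and of at least 8-fold for 53 higher and 4 lower probes. The values of the 2 days did not overlap for 49.4% of probes, where chance gives 10%. The median change over the tested probes was -0.05, a value that the quantile normalization of the deposited values keeps small. Leaving out 1 rat moved the count of changed probes to 2338 without day 1 rat 1, 2016 without day 3 rat 6, 2427 without day 3 rat 4 and 2093 without day 3 rat 7. Array weights gave 6123 changed probes. Without day 1 rat 3 and day 3 rat 6, whose arrays had high skeletal muscle signal, 4029 probes changed and 3230 of these were also among the 3694.

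The largest rises after Cthrc1 and Col1a1 were those of Lum, Col5a1, Col3a1, Olfml3, Aspn and Lrrc15, among genes that passed the test without overlap of the days. Lum encodes a small proteoglycan that binds collagen fibrils, and it rose 26.6-fold. Without day 1 rat 3, the log2 change of Lum went from 4.74 to 5.49 and that of Col3a1 from 4.43 to 5.04. Lrrc15 showed little spread, with 6.52 ± 0.06 at day 1 and 10.79 ± 0.11 at day 3 (SD, n = 3; change 4.27 ± 0.112 SE, limma adjusted p = 2.47e-05). The day 1 signal of Lrrc15 lay near the array median of 6.47. Its small day 1 spread may therefore be that of dim signal, and its change may be understated. The largest falls by the same rule were those of Gnmt, Ltb, Retnlg, Ccl4, Ppbp, Tcp11, Hdc and Olah. Gnmt, a glycine methyltransferase, fell 11.8-fold, and the cytokine gene Ltb fell 9.13-fold. Olah fell 7.41-fold and Tcp11 fell 7.57-fold. Ppbp, a platelet chemokine, lay below the array median on every day 3 array, and its signal was at least 6.43-fold lower at day 3.

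**Figure D1:**
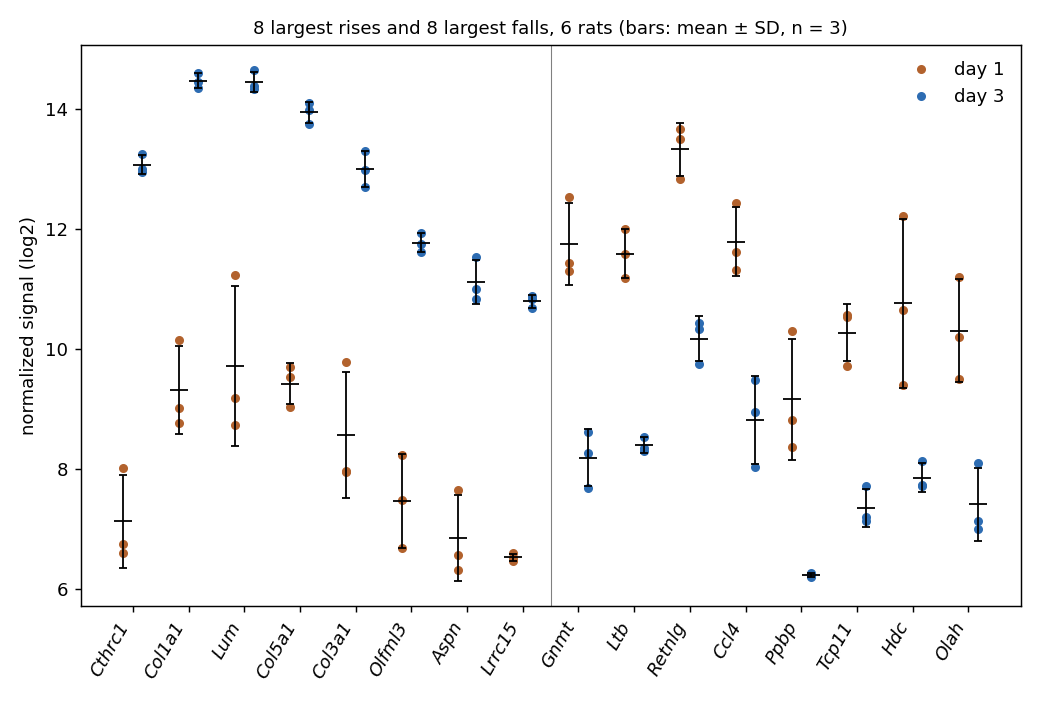
Normalized signal (log2, vertical axis) of the 8 genes with the largest rises and the 8 with the largest falls, with a point for each rat and bars for the mean ± SD (n = 3). Cthrc1 lies at 13.06 on average at day 3 against 7.12 at day 1, and Gnmt at 8.18 against 11.74.

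In the list of fibrillar collagens and matrix glycoproteins, 24 of 27 measured members rose and 2 fell, with a median change of 2.64 (camera adjusted p = 1.8e-10; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone, 24 rose and 3 fell. Col5a1 rose by 4.52 and Col3a1 by 4.43, while Vcan fell by 1.03 and Fbln1 fell by 0.75. Among the enzymes and factors that process and cross-link collagen, 15 of 20 rose and none fell, with a median change of 1.30 (camera adjusted p = 1.75e-06; adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone, 16 rose and 1 fell. Pcolce, an enhancer of procollagen cleavage, rose 14.8-fold, and Sparc, a collagen-binding glycoprotein, rose 10.9-fold. Lox, which cross-links collagen, rose by 2.89, and the collagen chaperone Serpinh1 had a change of -0.16 (adjusted p = 0.361).

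Of 14 measured fibroblast markers, 8 rose and 1 fell, with the same counts adjusted over the list alone (median change 1.23, camera adjusted p = 0.00829; adjusted p = 0.547 with an estimated correlation). Mfap5, a microfibril protein, rose 12.8-fold, and Fap, a surface protease of activated fibroblasts, rose 10.1-fold. S100a4 fell by 0.38. Of 17 genes of resident subcutaneous tissue, 10 rose and none fell (median change 1.52), the same way as the matrix, fibroblast and endothelial lists. Of 10 contractile genes of myofibroblasts and smooth muscle, 3 rose, and 6 rose when adjusted over the list alone (median change 1.48, camera adjusted p = 0.0197; adjusted p = 0.413 with an estimated correlation). Tpm1, which skeletal muscle also expresses, had a change of 0.49 (adjusted p = 0.823). Smtn rose 7.83-fold and Myl9 rose by 1.81. Cspg4, a surface proteoglycan rather than a contractile protein, rose 3.91-fold. Acta2, Myh11 and Cnn1 were listed but were not among the 10 measured. In the Wnt and Tgf-beta pathway list, 11 of 29 members rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.377 with an estimated correlation). Sfrp2 and Sfrp4, secreted antagonists of Wnt signalling, rose 13.5-fold and 7.51-fold, while Tgfb1 fell by 1.01 and Smad7 by 1.31. With only probes above the median on all 6 arrays, the Wnt and Tgf-beta list had adjusted p = 0.0624.

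Of 37 cell cycle genes, 31 rose and none fell, also when adjusted over the list alone, with a median change of 1.39 (camera adjusted p = 3.68e-13; adjusted p = 0.377 with an estimated correlation). The mitotic genes Ccnb2 and Tpx2 rose 7.78-fold and 7.05-fold, and Cdk1 rose by 2.75. Ccnb2 went from 9.07 ± 0.33 to 12.03 ± 0.17 (SD, n = 3). Pcna, a clamp of the replication fork, had a change of -0.09 (adjusted p = 0.557).

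In the list of hypoxia response and glycolysis genes, 15 of 25 fell and 1, Pfkm, rose, with a median change of -0.97 (camera adjusted p = 1.99e-05; adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone, 21 fell and 1 rose. Ankrd37, a hypoxia-induced gene, fell 3.33-fold, Pkm, a pyruvate kinase, fell 3.31-fold, and Ldha fell by 0.97. Of 29 oxidative phosphorylation genes, 8 rose and none fell, but 0 passed in limma when adjusted over the list alone and 11 had an unadjusted p under 0.05 (median change 0.20, camera adjusted p = 0.0214; adjusted p = 0.678 with an estimated correlation). Fry gave adjusted p = 0.163, cyclic loess gave 0.143, and the fit without day 1 rat 2 gave 0.104. Ndufa5 rose 2.44-fold and Atp5po rose 1.59-fold. Ndufa5 had adjusted p = 0.0868, 0.0856, 0.0663 and 0.0936, and Atp5po 0.0635, 0.07, 0.0539 and 0.0622, without day 1 rat 1 and without day 3 rats 6, 4 and 7.

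Of 17 measured neutrophil markers, 13 fell and 1 rose, with the same counts adjusted over the list alone (median change -1.53, camera adjusted p = 3.54e-05; adjusted p = 0.377 with an estimated correlation). Mmp8, a neutrophil collagenase, fell 5.88-fold, and Elane, neutrophil elastase, fell 5.75-fold. Lcn2, which many cell types also make, rose by 1.37. Of 22 inflammatory cytokines and mediators, 15 fell and none rose, and adjusted over the list alone 17 fell and 1 rose (median change -1.23, camera adjusted p = 2.09e-06; adjusted p = 0.377 with an estimated correlation). Ptges, a prostaglandin E synthase, fell 5.08-fold, and Nos2, the inducible nitric oxide synthase, fell 4.21-fold. Il1a fell by 2.05 and Tnf fell by 1.35, while Il6 had a change of -0.56 (adjusted p = 0.0526). Of 17 genes widely used as leukocyte markers, 14 fell (median change -1.28), the same way as these 2 lists and the chemokine and alternative activation lists. The fall was not seen in every leukocyte list. Markers of T, B and NK cells had a median change of -0.07 and macrophage markers one of 0.03. Several of the T, B and NK markers were dim at day 1, such as Cd3e (6.9) and Klrd1 (6.91), near the array median of 6.47. A fall of such genes can hardly show, so the median does not exclude a fall of lymphocyte genes.

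Of 26 chemokines, 11 fell and 5 rose, and adjusted over the list alone 16 fell and 5 rose (median change -0.98, camera adjusted p = 0.0169; adjusted p = 0.377 with an estimated correlation). Ccl4 fell 7.84-fold. The members that rose were Cxcl13, Cxcl12, Cxcl9, Ccl11 and Cx3cl1, and Cxcl13, which attracts B cells, rose 8.36-fold. The list had adjusted p = 0.0712 without day 1 rat 3, and 0.0597 without day 1 rat 3 and day 3 rat 6. Of 23 immediate early and heat shock genes, 11 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose (median change -0.73, camera adjusted p = 0.00525; adjusted p = 0.413 with an estimated correlation). Ier3 fell 3.34-fold and Atf3 fell by 1.59. Hspb8, a small heat shock protein, rose 3.91-fold, with adjusted p = 0.0606, 0.0626 and 0.0509 without day 1 rat 1, day 3 rat 6 and day 3 rat 7.

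Macrophage markers moved both ways. Of 17 measured, 6 rose (C1qa, C1qb, C1qc, Apoe, Trem2 and Cd163) and 3 fell (Cd14, Ctsd and Fcgr1a), and adjusted over the list alone 7 rose and 3 fell (median change 0.03, camera adjusted p = 0.735). C1qa and C1qc, which encode chains of the first complement component, rose 5.43-fold and 5.37-fold. C1qa had adjusted p = 0.0533, 0.0539 and 0.0523 without day 1 rat 1, day 3 rat 6 and day 3 rat 7. C1qc had adjusted p = 0.0693, 0.0542, 0.0708 and 0.0706 without day 1 rat 1, day 1 rat 2, day 3 rat 6 and day 3 rat 7, and its change went from 2.42 to 3.09 without day 1 rat 3. Of 18 genes of alternative activation and efferocytosis, 10 fell and 2 rose, and adjusted over the list alone 10 fell and 3 rose (median change -0.66, camera adjusted p = 0.0109; adjusted p = 0.377 with an estimated correlation). Chi3l1 fell 5.45-fold, the chemokine Ccl22 fell 4.29-fold and Arg1 fell by 1.10. Of 15 complement components, 10 rose and 1 fell, with the same counts adjusted over the list alone (median change 2.15, camera adjusted p = 0.00525; adjusted p = 0.413 with an estimated correlation). C1s and C1r, proteases of the classical pathway, rose 7.51-fold and 6.02-fold, and Cfp fell by 1.03. C1r had adjusted p = 0.0534 without day 1 rat 1 and 0.0528 without day 3 rat 6. Without day 1 rat 3, C1s went from 2.91 to 3.61 and C1r from 2.59 to 3.27.

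Of 20 interferon-stimulated genes, 8 fell and 1, Ifi27, rose, with the same counts adjusted over the list alone (median change -0.61, camera adjusted p = 0.0214; adjusted p = 0.555 with an estimated correlation). Ifit1 fell 6.52-fold and Oas1a fell 2.56-fold. Fry gave this list adjusted p = 0.124, and camera gave 0.111 without day 1 rat 1 and 0.0647 without day 3 rat 6. Of 16 genes of MHC class II and dendritic cells, 3 rose and 5 fell, and adjusted over the list alone 5 rose and 6 fell (camera adjusted p = 0.49, fry adjusted p = 0.0482). RT1-DMa fell 2.62-fold and Cd86, a costimulatory ligand, fell 2.13-fold, while RT1-Ba, RT1-Da and RT1-Db1 rose. Of 14 markers of T, B and NK cells, 1 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.738). Cd3d fell 1.71-fold. Cd4 was at least 1.45-fold higher at day 3, with adjusted p = 0.0554, 0.0708 and 0.0764 without day 1 rat 1, day 3 rat 6 and day 3 rat 7, and 0.0717 without the arrays of day 1 rat 3 and day 3 rat 6.

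Of 12 endothelial markers, 8 rose and none fell, also when adjusted over the list alone (median change 1.00, camera adjusted p = 0.0109; adjusted p = 0.413 with an estimated correlation). Vwf, a clotting protein stored in endothelial cells, rose 4.18-fold. Emcn rose 3.68-fold, with adjusted p = 0.0748, 0.0604 and 0.0657 without day 3 rats 6, 4 and 7, and a change of 1.29 in place of 1.88 without day 1 rat 2. Of 16 angiogenic factors, 5 rose and none fell, also when adjusted over the list alone (median change 0.40, camera adjusted p = 0.048; adjusted p = 0.413 with an estimated correlation). Thbs2, whose protein inhibits angiogenesis, rose 9.60-fold, and Vegfc rose by 2.28. Vegfa had a change of -1.22 (adjusted p = 0.0681). Cxcl12 rose 6.78-fold, with adjusted p = 0.0939, 0.0881, 0.093, 0.0712 and 0.093 without day 1 rat 1, day 1 rat 2, day 3 rat 6, day 3 rat 4 and day 3 rat 7, and 0.0564 with no filter. Without day 1 rat 3 its change went from 2.76 to 3.74. The angiogenic list had adjusted p = 0.0678, 0.0509 and 0.078 without day 1 rat 1, day 1 rat 2 and day 3 rat 4. It had 0.105 with probes above the median on all 6 arrays, 0.0548 with cyclic loess and 0.0589 with the mean of a gene's probes.

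Of 22 matrix proteases and their inhibitors, 8 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0701). Mmp23 rose 5.83-fold, and Mmp9, a gelatinase also held by neutrophils, fell 5.32-fold. The list had adjusted p = 0.0177 with no filter and 0.04 with fry. Of 12 osteoblast and mineralisation genes, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.877). Pth1r, the receptor of parathyroid hormone, rose 4.13-fold, and Alpl, an alkaline phosphatase, fell by 0.89. Tnfrsf11b, a decoy receptor that limits osteoclast formation, rose 4.52-fold, with adjusted p = 0.0584 without day 1 rat 1 and 0.0546 without day 3 rat 7, and a change of 2.77 in place of 2.18 without day 1 rat 3. Of 10 genes of osteoclasts and multinucleated giant cells, 3 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.158, fry adjusted p = 0.0167). Oscar fell 4.18-fold, and Ctsk had a change of -0.09 (adjusted p = 0.814). Of 12 progenitor genes, 3 rose and 2 fell, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.437). Nes, an intermediate filament of progenitor cells, rose 5.31-fold, and Cxcr4 fell by 1.70.

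**Figure D2:**
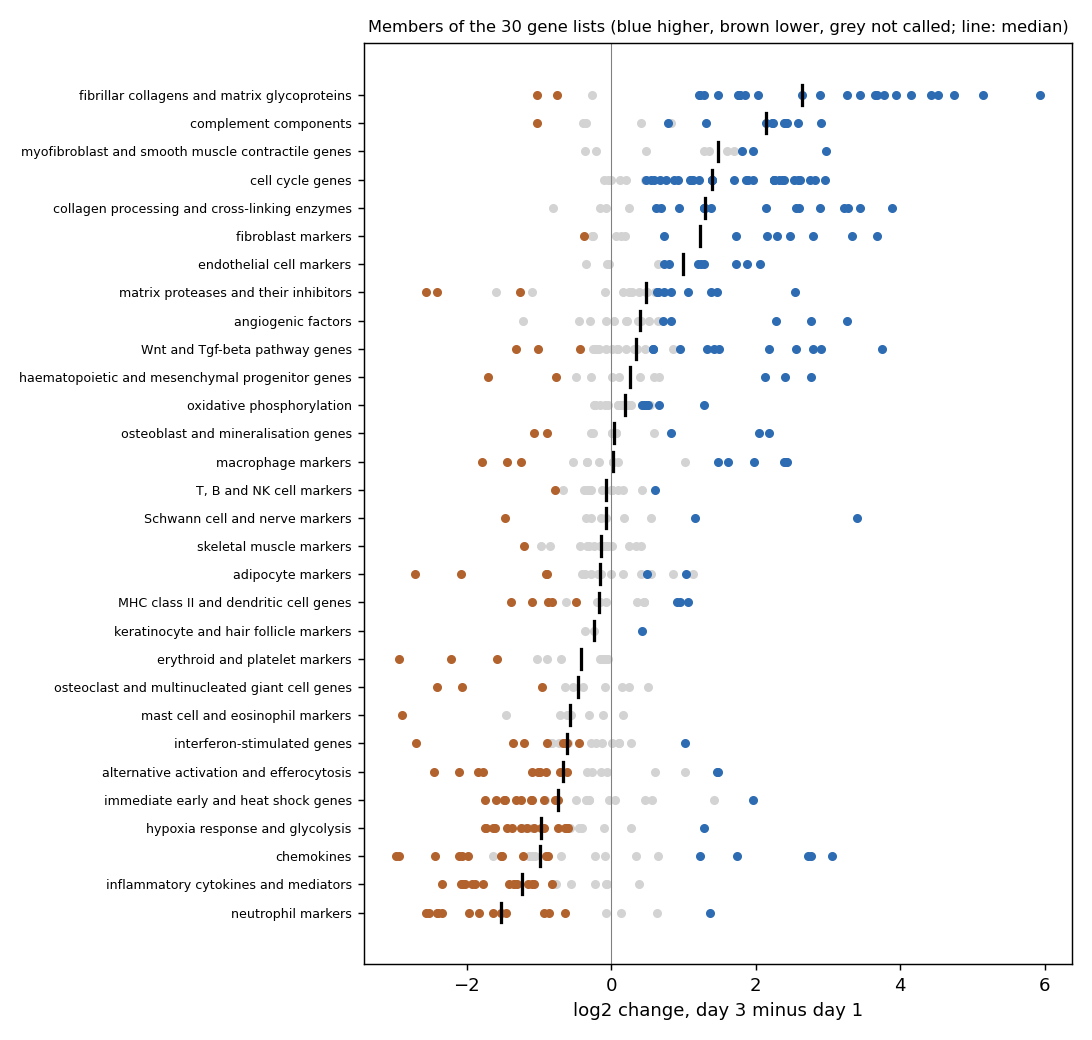
Log2 change of each measured member (horizontal axis, day 3 minus day 1) of the 30 gene lists (rows, ordered by median), with blue points for members called higher, brown for members called lower and grey for the rest, and a black line at the list's median. The matrix list has the highest median, 2.64, and the neutrophil list the lowest, -1.53.

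Skeletal muscle genes were high on 1 array of each day. Acta1, the actin of skeletal muscle fibres, had 13.59 in day 1 rat 3 and 13.45 in day 3 rat 6, against 6.39, 7.51, 8.82 and 6.49 in day 1 rats 1 and 2 and day 3 rats 4 and 7. Ckm, the muscle creatine kinase, had 12.54 and 12.00 on the same 2 arrays. Of 17 measured muscle markers, 1 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.522). Tnnc1 fell 2.30-fold, with adjusted p = 0.0538 without day 1 rat 1. The muscle list had adjusted p = 0.0288 without day 3 rat 6, with lower values at day 3.

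**Figure D3:**
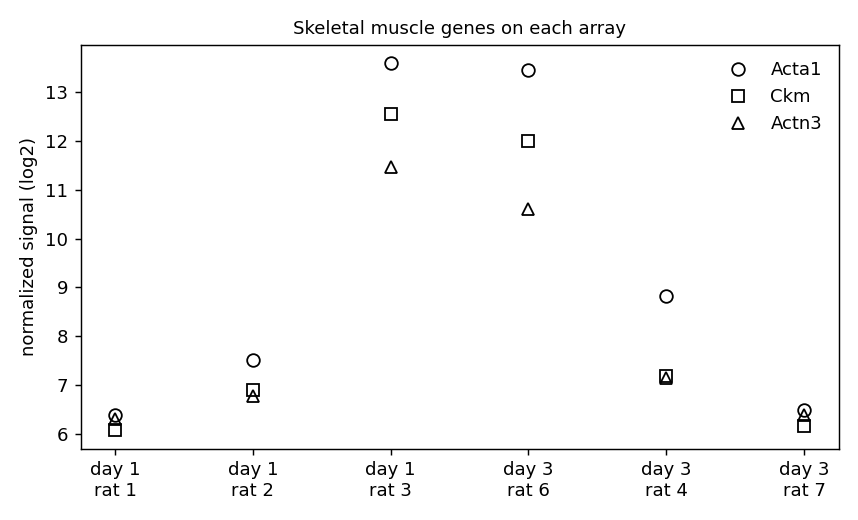
Normalized signal (log2, vertical axis) of Acta1, Ckm and Actn3 on each of the 6 arrays (horizontal axis), with 1 marker shape for each gene. Actn3 has 11.47 in day 1 rat 3 and 10.61 in day 3 rat 6, and at most 7.14 on the other arrays.

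Markers of other cell types of skin and blood were also measured. Of 18 adipocyte markers, 2 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.49). Scd, a fatty acid desaturase, fell 6.53-fold, and Dgat2, an enzyme of triglyceride synthesis, fell 4.22-fold. Of 9 mast cell and eosinophil markers, 1 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.0636). Hdc, which makes histamine, fell 7.47-fold, with adjusted p = 0.0542 without day 3 rat 7. Its change went from -2.90 to -2.17 without day 1 rat 3 and to -3.58 without day 1 rat 1. Day 1 rat 3 stood apart for this list, with a median 1.43 above day 1 rats 1 and 2. Hdc had 12.21 there against 9.40 and 10.65, Tpsab1 9.52 against 7.89 and 7.82, and Cpa3 8.75 against 7.17 and 7.15. The list passed in some settings only, with adjusted p = 0.0209 without day 1 rat 1, 0.0367 without day 3 rat 7, 0.038 with no filter, 0.0497 with an intensity trend and 0.0482 with offset 16. It had 0.166 without day 1 rat 3, 0.216 with probes above the median on all 6 arrays and 0.234 with array weights. Of 12 erythroid and platelet markers, 3 fell and none rose, also when adjusted over the list alone (median change -0.42, camera adjusted p = 0.0214; adjusted p = 0.413 with an estimated correlation). Nfe2 fell 4.67-fold and Hbb-b1 fell by 1.58, while the related globin genes Hbb and Hba-a1 had changes of -0.10 and -0.14. Values of such near-identical genes are uncertain, since their probes can share signal. With probes above the median on all 6 arrays, this list had adjusted p = 0.0655. Of 9 Schwann cell and nerve markers, 2 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.893). Its median change was -0.08 and its mean 0.33. Gap43, a protein of growing axons, rose 10.7-fold, and Egr2, a transcription factor, fell 2.77-fold. Of 3 measured keratinocyte and hair follicle markers, 1 rose, also when adjusted over the list alone (camera adjusted p = 0.893). This was Tp63, at least 1.14-fold higher at day 3, with adjusted p = 0.0533, 0.0623, 0.0571 and 0.07 without day 1 rat 1, day 3 rat 6, day 3 rat 4 and day 3 rat 7, and 0.0551 without the arrays of day 1 rat 3 and day 3 rat 6. The keratinocyte list had a median change of -0.24, camera pointed down and fry up.

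Of the 30 lists, 18 were called by camera with a preset correlation of 0.01, 10 higher and 8 lower at day 3. With an estimated correlation, camera called 0, and 3 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes, called 19 lists, 16 of them among the 18. The arrays correlated at 0.96 to 0.982 within day 1, 0.987 to 0.993 within day 3 and 0.87 to 0.96 between the days (Pearson, over the tested probes, which are not independent replicates). The ranges crossed at day 1 rat 3. Its array correlated at 0.9765 and 0.9597 with day 1 rats 1 and 2. With day 3 rats 6, 4 and 7 it correlated at 0.9494, 0.9604 and 0.9514. On the first principal component, with 80.4% of the variance, day 1 rat 3 lay at -15.54, nearer to day 3 (32.02 to 49.08) than day 1 rats 1 and 2 (-43.29 and -62.6).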

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

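Cyclic loess, offset 16 and the omission of 2 arrays were chosen after seeing the data. No named gene turned its direction, and no list turned where it was called in either setting. Among uncalled lists, 5 (muscle, keratinocyte, adipocyte, Schwann and lymphocyte) turned direction in 10 values in all, with adjusted p of 0.597 to 0.995. Of 66 named genes, 53 kept their side of the threshold wherever they had a value, 9 genes had none with the filter on all 6 arrays, and 42 of 915 values lost the threshold. The 3694 changed probes (1937 higher, 1757 lower) became 6123 with array weights (3027 higher, 3096 lower), 1593 at adjusted p under 0.01 and 1563 at a change of at least 2-fold. Leaving out 1 rat gave 2016 to 4902 changed probes, 1135 to 2497 higher and 881 to 2405 lower. The cause was not tested, except that the stricter thresholds call fewer by construction.

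With an estimated correlation no list passed. Adjusted p was 0.377 for the neutrophil, alternative activation, matrix, collagen processing, chemokine, inflammatory, cell cycle and Wnt and Tgf-beta lists, and 0.413 for the endothelial, angiogenic, contractile, complement, hypoxia, erythroid and immediate early lists. It was 0.547 for fibroblast, 0.555 for interferon and 0.678 for oxidative phosphorylation genes. Fry gave 0.0482 for MHC class II, 0.04 for proteases, 0.0167 for osteoclast, 0.124 for interferon and 0.163 for oxidative phosphorylation genes. No filter gave 0.0177 for proteases and 0.038 for mast cells. The filter on all 6 arrays gave 0.105 for angiogenic, 0.0624 for Wnt and Tgf-beta and 0.0655 for erythroid genes. Cyclic loess gave 0.0548 for angiogenic and 0.143 for oxidative phosphorylation genes, and the mean of a gene's probes gave 0.0589 for angiogenic genes. An intensity trend gave 0.0497 and offset 16 gave 0.0482 for mast cells, and without the 2 arrays with muscle signal chemokines had 0.0597. The cause was not tested. Leaving out 1 rat gave 0.0215 to 0.078 for angiogenic, 0.004 to 0.0712 for chemokine, 0.0043 to 0.111 for interferon, 0.00407 to 0.104 for oxidative phosphorylation, 0.0288 to 0.995 for muscle and 0.0209 to 0.166 for mast cell genes.

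No paired analysis was possible because the rats of the 2 days carry different numbers. The planned scaling to an upper percentile and cyclic loess in place of quantile normalization were not run, since the deposited values already hold it. The planned normexp with offset 50 is the setting reported, and the deposited values as log2 are the setting without background correction. A chip block was not run because no label names a chip. Signal near background limits what dim probes can show.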

Other observations

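Chosen after the result was seen were the tests of the pan-leukocyte, cholesterol and secretory lists, of the contractile genes, of the day, of the macrophage markers, of the single mixing fraction and of the cell cycle genes in rat 3. Many genes expressed across several leukocyte types were lower at day 3. Of 17 measured genes of this pan-leukocyte list, some of which, such as Itgam, are mainly myeloid, 14 fell and none rose, with a median change of -1.28 (camera p = 2.22e-08; p = 0.109 with an estimated correlation). Ptprc, the leukocyte common antigen, fell by 2.19 and Itgam fell by 1.87. Of 27 protein folding and secretory pathway genes, tested as a hypothesis beside the rise of collagen genes, 11 rose, 1 fell and 15 were not called, with a median change of 0.296 (camera p = 0.000588; p = 0.2 with an estimated correlation). Fkbp9 rose by 3.49 and Rcn3 by 3.48, while the general folding genes Calr, Hsp90b1, Canx, Pdia3 and Pdia4 were not called (0.124, -0.126, -0.388, 0.178 and 0.201). The hypothesis that the fall of Scd belongs to lower signal of cholesterol and fatty acid synthesis genes was not borne out for the genes measured. Of 11 measured of 21 listed, 3 rose and 1 fell, which was Scd itself (camera p = 0.856, and p = 0.94 with an estimated correlation). Besides Scd, only Acly, Fads1 and Fads2 of the 11 stand for fatty acid synthesis, so lower fatty acid synthesis was hardly tested. Fads1 rose by 1.58. Triglyceride synthesis was not tested as a list, and Dgat2, an enzyme of it, fell by 2.08.

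Of the 10 splits of the 6 arrays into 3 and 3, the real one, 1 of 10, gave 3694 changed probes and 1563 changed at least 2-fold, and the highest of the other splits gave 0 for both (limma; at most 721 at an unadjusted p under 0.05). For gene lists called by camera with the preset correlation, the real split gave 18 and the highest other 14. With 10 splits no share under 0.05 can be reached. Each of the other splits puts arrays of both days in both groups. The difference between the days then adds to the spread within groups and lowers the number of calls. The 0 is therefore no measure of what chance alone gives. Part of the difference between the days also stays between the groups, and what lies behind the 14 lists was not tested.

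Skeletal muscle genes were high in day 1 rat 3 and day 3 rat 6, where 11 of 17 measured muscle markers lay at least 2-fold above the other 4 arrays. The day does not account for this, since rats of 1 day differed: Acta1 had 13.59 in day 1 rat 3 against 6.39 and 7.51 in its day mates, and 13.45 in day 3 rat 6 against 8.82 and 6.49. That only 1 of the 17 had days without overlap restates the pattern and adds nothing. Contractile genes of myofibroblasts are argued against for day 3 rat 6 only, and for the 10 genes measured, which lack Acta2, Myh11 and Cnn1. Their median rise on that array over its day mates was 0.389, against 2.57 for the muscle list. Day 1 rat 3 was not tested in this way. Muscle tissue carried with the implant stays a candidate explanation, but the test written before its result did not decide it: 2 of 7 measured genes of a second muscle list were raised in both arrays, too few of its 34 genes for more.

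Day 1 rat 3 lay nearest to the day 3 arrays on the first principal component, at -15.54 against -43.29 and -62.6 for the other day 1 rats and 32.02 to 49.08 at day 3. If RNA of a day 3 implant were the whole difference, every gene would need the same share of day 3 signal. The median share was 0.0897 for 24 matrix genes and 0.367 for 10 complement genes (permutation p over genes = 0.0063). The permutation treats genes of 1 array as replicates, though genes are not independent, and it holds no spread between rats. It therefore cannot decide whether mixing was the whole difference. Mixing in whole or in part stays open. A bound written before its result was met, but this does not favour mixing. Any array that lies between the others would tend to meet it, whatever the cause. Day 1 rat 2 alone also made the bound loose: 17 probes of day 1 rat 3 lay at least 2-fold outside the other 5, against 13 and 110 for day 1 rats 1 and 2 and 15, 1 and 6 for day 3 rats 6, 4 and 7. Resident tissue carried with the implant also stays open: on this array, with its high muscle signal, the median excess over rats 1 and 2 was 1.26 for 17 resident tissue genes and 1.43 for the mast cell list, but the resident genes rose at day 3 as well (median change 1.52, camera p = 0.000238; p = 0.298 with an estimated correlation). A further advanced response in this rat cannot be told apart from these, because rat and array are the same. On the log2 scale, 26 cell cycle genes had moved a median 0.251 of the way to day 3. The 1674 genes that changed at least 2-fold in a fit without this array had moved 0.396. These genes were chosen by the distance of rats 1 and 2 from day 3, and the same rats were the starting point. Such a choice by itself tends to place a left-out day 1 rat nearer to day 3. Neither rat 1 nor rat 2 was left out in the same way, so there is no value to compare with. The shares of day 3 signal given above were taken on the linear scale, with genes chosen in the same way. On the log2 scale the matrix genes had moved 0.313 and the complement genes 0.625. Mast cell genes ran away from day 3 (Hdc 12.21, against 9.40 and 10.65 in rats 1 and 2 and 7.71 to 8.13 at day 3).

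Pan-leukocyte genes fell while C1q and other macrophage genes rose. The pan-leukocyte median change of -1.28 lay near those of the neutrophil list (-1.53) and the inflammatory list (-1.23). Whether these 2 lists fell beyond the fall of the pan-leukocyte genes was not tested. A lower share of leukocyte RNA alone is argued against, since it would lower both, and of 17 macrophage markers 6 rose and 3 fell (Cd14, Ctsd and Fcgr1a). Tissue carried in by the 2 arrays with high muscle signal is argued against, since C1qa, C1qb and C1qc had a median change of 2.94 without them and 2.42 with all 6 arrays. A lower share beside a change of the macrophages between the days stays open, and it was not tested.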
